A study of Danio rerio with 3 samples.

How the data were processed

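Bulk RNA-seq was available for 3 libraries of a single group, muLECs from adult wildtype zebrafish brains. Per the labels' protocols, brain tissue was digested with Liberase, an enzyme blend, cells carrying a lyve1 DsRed reporter were collected by fluorescence-activated sorting, RNA was amplified, and each library used 6 brains. The file columns carry another cell name, pvLEC, and were matched to the samples by replicate number. No control or comparison population belongs to the group, so no comparison between groups was made.

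The values deposited by the authors are counts, whole-number reads per gene and library for 32105 Ensembl gene IDs, with no normalization seen in them. The submitters' processing notes name the GRCz10 build, bcl2fastq and R 3.2.2. The aligner and the counting program are not given in the sources used here. The authors also deposited a YuGene score per gene and library. Recomputed from the counts as 1 minus the cumulative share of log2(CPM + 1) over genes ordered by level, these scores differed from the deposited values by at most 2.21e-13. No row of the count table lacked a gene ID.

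Library depth was 36044297, 35168650 and 34307745 reads in replicates 1, 2 and 3. The labels say nothing of separate sort days, and the replicates are separate pools of brains. Amplified reads are not independent molecules, so intervals and the floor of 3 reads, which came to 0.0794, 0.107 and 0.0729 CPM, cover counting error alone. Gene symbols came from a table pairing gene IDs with names, which gave a symbol for 26269 IDs. Many symbols in it are written in human style and some are shared by several zebrafish gene copies. Gene coordinates and lengths of the build were not used here, so positions are not given and counts were not divided by gene length. Reads split between near-identical copies could not be checked, and the strand setting of the counting is not given in the sources used here.

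Except where stated, CPM values were scaled with edgeR 4.0.16 TMM factors, which were 1.05, 0.796 and 1.20. Genes with at least 10 reads in at least 2 libraries were tested. An edgeR quasi-likelihood test of the intercept, with the log of each library's median count over the tested genes as offset, asked whether a gene stood above or below the median gene, at a Benjamini-Hochberg adjusted p under 0.05. The function glmQLFTest does not accept a design with a single column, so its steps were written out from the glmQLFit output: the deviance with the intercept at 0, less the fitted deviance, over the posterior quasi-likelihood variance, with the bound by the Poisson test. Standard errors came from the fitted information and that variance. Tested on counts simulated for 7111 genes, the procedure called 94% of 50 genes placed 16 times above the median and 56% of 50 placed 4 times above. It called 2% of 50 genes placed at 0.25 of the median, 22% of 50 at 0.0625, and 1.5% of 200 genes placed at the median. The placed genes were drawn at random and kept their own dispersion, while spread depends on level in the data. These rates therefore need not hold for real genes at those levels.

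The 28 gene lists, 18 for cell types and 10 for functions, were fixed before the data were examined, as was the rule for naming genes. The rule for matching symbols was set after the symbols of the table were seen. Symbols were matched exactly, ignoring case. Otherwise the final a or b was dropped and the capital stem used, where the table gave it no more IDs than the list named copies. This placed 610 of 693 symbols. Of the genes to be named whatever their level, pecam1 and mpeg1.1 were not matched. Lists with at least 3 tested members were compared with all other tested genes by camera in limma 3.58.1, on log2(CPM + 1) centred on each library's median gene, with a preset inter-gene correlation of 0.01. For camera, the list medians over the median gene and the random lists, CPM used plain library size without TMM factors. Of 200 random lists of 15 tested genes, 2.5% had p under 0.05. Genes drawn at random need not vary together as members of a chosen list may, so this rate does not cover such lists. A percentile among 10000 random lists of equal size describes where each median lay. Differences between the medians of 2 lists, on log2(CPM + 1) with undetected members kept, were tested by an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25.

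The naming rule took the 15 highest genes with a symbol outside mitochondrial and ribosomal protein genes, up to 4 highest members of each list, a set of marker and growth factor genes, and the 8 genes with the largest ratio between libraries among those of at least 50 CPM. Genes outside the rule are marked as chosen after their values were seen. The alternatives covered DESeq2 1.42.0, limma-trend, other filters, scalings, pseudocounts and reference levels, the YuGene scores and leaving out each library. Added after seeing the data were the removal of counts under 2% of the same gene's count in another library, all copies of ambiguous names, the lymphatic list without lyve1b, a 3-read floor, and Fisher's exact test of list detection. Analyses ran in R 4.3.3 and figures were drawn with matplotlib 3.10.9.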

Results

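RNA was sequenced from muLECs of the adult zebrafish brain, spelled out in the study's title as mural lymphatic endothelial cells, whose part in the growth of meningeal blood vessels the title addresses. The cells were sorted from wildtype fish on a lyve1 reporter and formed 1 group of 3 libraries, each from 6 brains. The libraries held 36044297, 35168650 and 34307745 reads in genes. With no other cell population for comparison, levels were described within the sorted cells, against the median detected gene and against markers of other brain cells.

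At least 10 reads in 2 or more libraries were found for 7111 genes, of which 4108 reached 10 reads in all 3 libraries. A further 4998 genes reached 10 reads in a single library. The nuclear non-coding RNA malat1 took 27.6% ± 6.16 of all reads (SD, n = 3), and the 10 highest genes of each library together took 52.6% ± 2.10. Mitochondrially encoded genes took 5.96% ± 0.367 and ribosomal protein genes 0.979% ± 0.143. Mitochondrial and ribosomal protein genes aside, the next highest genes with a symbol were epd, an ependymin, at 66601 CPM ± 27000 (SD, n = 3), and GLUL, a glutamine synthetase, at 49442 CPM ± 8834. Then came GGCT at 24734 CPM ± 10381, si:ch211-276i12.12 at 17245 CPM ± 1718, the small GTPase gene rap1b at 14721 CPM ± 8644, the cofilin gene CFL1 at 11961 CPM ± 6760, MIDN at 10551 CPM ± 5441 and APLP2 at 9044 CPM ± 4300. The selenium carrier gene selenop stood at 7383 CPM ± 517, sgpp1a at 6593 CPM ± 4505, the heme oxygenase gene HMOX1 at 5061 CPM ± 2979, cd99 at 5009 CPM ± 3202, the translation factor gene eif4a1a at 4896 CPM ± 2355, and mcl1b at 4841 CPM ± 2444. Without replicate 2 the means of sgpp1a and cd99 were 4098 and 3254 CPM.

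Spread between the libraries was widest among genes of low level. Across the 7111 genes, Pearson's r of log2(CPM + 1) was 0.531 for replicates 1 and 2, 0.691 for 1 and 3, and 0.616 for 2 and 3, and Spearman's rho was 0.473, 0.639 and 0.560. These are correlations across genes, which are not independent replicates. Counts of each pair differed far beyond sampling noise, with a chi-square per degree of freedom of at least 572.5, so no library was the same sequenced library read again. The median coefficient of variation was 1.01 for genes under 10 CPM, 0.863 from 10 to 50 CPM, 0.420 from 50 to 200 CPM, 0.313 from 200 to 1000 CPM and 0.435 at 1000 CPM and more.

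By the edgeR quasi-likelihood test, 1666 genes stood above the median gene, 88 stood below it and 5357 did not pass. The number below is the less certain part. In simulated counts, 22% of genes at 0.0625 of the median were called, and DESeq2 called 0 genes below the median, with 75 at an unadjusted p under 0.05. Without replicate 3, 4444 genes were tested, 937 stood above and 215 below, and 321 stood below without replicate 1 and 480 without replicate 2. Of the 88, only 23, 56 and 17 were still tested without replicates 1, 2 and 3, so most of those below were other genes. Fewer low genes pass with 2 libraries, so the reference rises: named genes called higher moved by a median of -0.83, -0.65 and -1.04 on the log2 scale without replicates 1, 2 and 3. A call lost without a library therefore need not rest on a high level in that library. Of 290 tested list members, 0 were called below the median gene by edgeR (4 at an unadjusted p under 0.05), 0 by DESeq2 (0 at an unadjusted p under 0.05) and 3 by limma-trend. By Fisher's exact test at an adjusted p under 0.05, 10 of the 28 lists had a larger share of members tested than other genes with a symbol, and 0 a smaller share. Counts of list members above the median gene are to be read beside the 1666 of all 7111 tested genes.

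The lymphatic endothelial list stood high in the sorted cells. Of its 17 genes found in the file, 14 were tested, and 8 stood above the median gene, with 0 below and 8 above when adjusted over the list alone. MRC1 (ENSDARG00000102100), a mannose receptor and scavenger receptor, led the list at 4289 CPM ± 891 (SD, n = 3), a log2 ratio to the median gene of 8.45 ± 0.34 (SE, adjusted p = 5.12e-16, edgeR). The hyaluronan and scavenger receptor gene stab2 (ENSDARG00000045748) stood at 615 CPM ± 51.0, with a log2 ratio of 5.64 ± 0.29, and stab1 at 196 CPM ± 46.9. The growth factor ligand gene ANGPT2 stood at 322 CPM ± 96.2 and FLT4, the receptor for Vegfc, at 242 CPM ± 48.9. NR2F2, a venous and lymphatic transcription factor, stood at 64.7 CPM ± 3.70, with a log2 ratio of 2.39 that fell to 1.27 without replicate 3 and was then not called. Its level was even over the libraries (69.0, 62.5 and 62.7 CPM), and named genes called higher moved by a median of -1.04 without replicate 3. The sort used a lyve1 reporter, so lyve1b at 605 CPM ± 73.2 is a check of the sort rather than a result. Its other copy, lyve1a, had 0, 976 and 754 reads in replicates 1, 2 and 3.

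PROX1, the transcription factor that sets lymphatic identity, had 614, 1213 and 1 reads. It did not pass the test, at a log2 ratio of 0.73 ± 1.38 (SE, adjusted p = 0.852, edgeR). The transcription factor gene sox18 also did not pass, at 8.27 CPM ± 3.46. CCBE1, which acts in Vegfc processing, had 1, 0 and 269 reads. As a list, the lymphatic genes were higher on average than the other tested genes (median log2 level of 2.19 over the median gene, camera adjusted p = 0.00128), above 99.93% of random lists. The estimated-correlation adjusted p was 0.466, and over the alternatives, each changed alone, the adjusted p ran from 6.98e-08 to 0.466. The median of the list was 1.44 without replicate 1, with 13 members tested, and 3.24 without replicate 2, with 11 tested. With lyve1b left out, 7 of 13 tested members stood above the median gene (7 adjusted over the list alone), the median was 2.08 and the camera adjusted p was 0.00511 (estimated-correlation adjusted p = 0.515).

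General endothelial genes were also prominent. Of 24 pan-endothelial genes, 20 were tested and 11 stood above the median gene (11 adjusted over the list alone). The highest were clec14a at 373 CPM ± 83.1, MYCT1 at 340.1 CPM ± 121, ramp2 at 327 CPM ± 54.8 and EGFL7 at 318 CPM ± 72.9 (SD, n = 3). The ETS factor gene FLI1 stood at 58.2 CPM ± 25.1, a call lost without replicate 1 (log2 ratio of 0.97) and without replicate 3 (1.33). Its level was lowest in replicate 3 (87.1, 46.2 and 41.4 CPM), so the second loss does not rest on a high level there. In contrast, the vascular cadherin gene cdh5 had 0, 3 and 0 reads and kdrl, a Vegf receptor gene of blood vessels, had 3, 1 and 1, which is at or below the floor of 3 reads. The related receptor gene KDR had 680, 452 and 315 reads and did not pass the test, at a log2 ratio of 0.19 ± 1.23. The list as a whole ranked high (median log2 level of 2.12, camera adjusted p = 0.00128; estimated-correlation adjusted p = 0.316), a call also lost without replicate 3 (median 1.24, adjusted p = 0.131). The median was 1.42 without replicate 1 and 1.37 without replicate 2, and over the alternatives the adjusted p ran from 3.67e-06 to 0.316.

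**Figure D1:**
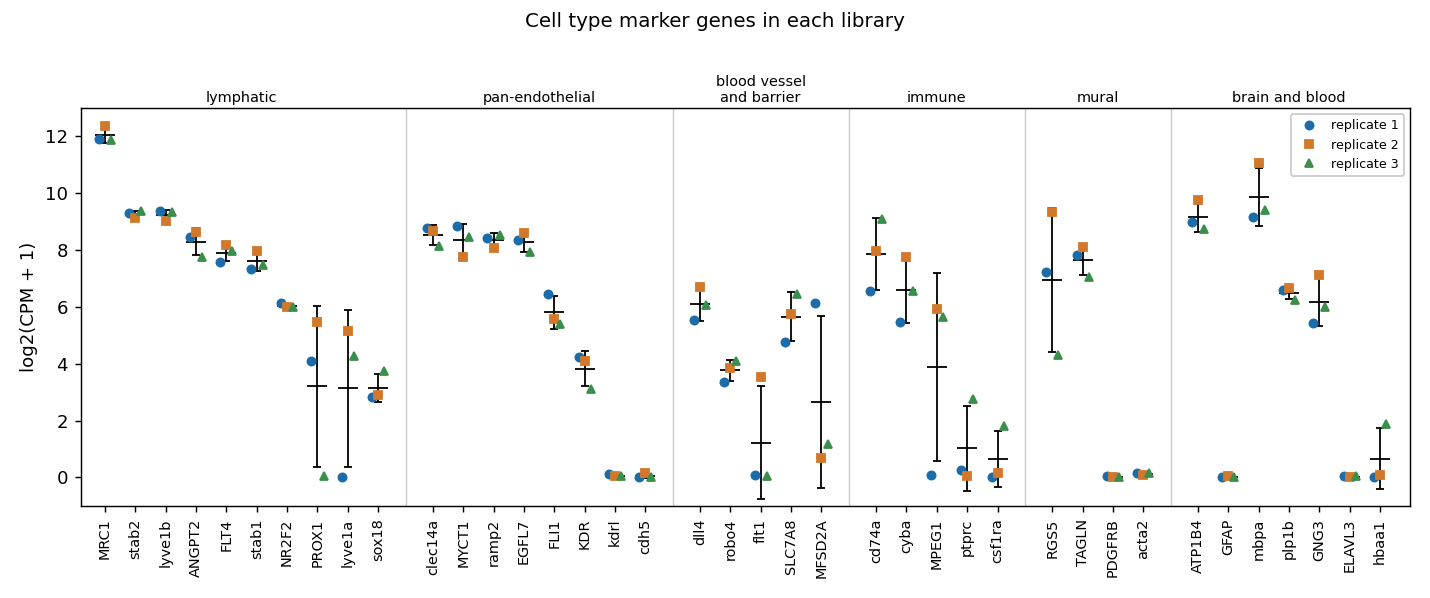
Level of named marker genes in each library, as log2(CPM + 1) on the vertical axis. Circles, squares and triangles are replicates 1, 2 and 3, and the horizontal bar and whiskers are their mean and SD (n = 3). MRC1 lies highest among the lymphatic genes at 4289 CPM, while kdrl, cdh5, PDGFRB, acta2, GFAP and ELAVL3 lie near 0 in every library.

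Among genes of blood vessels of the brain, dll4 and SLC7A8 stood out. Of 17 blood and arterial endothelial genes, 3 were tested. The Notch ligand gene dll4, at 71.0 CPM ± 28.9, stood above the median gene (log2 ratio of 2.54 ± 0.47, SE, adjusted p = 7.02e-05, edgeR), a call lost without replicate 3 (1.38). Its level was not highest in replicate 3 (45.2, 102 and 65.7 CPM), so that loss does not rest on a high level there. EFNB2 did not pass at 15.6 CPM ± 3.83, nor did robo4 with 352, 375 and 664 reads, and flt1 had 2, 296 and 2 reads. Of 11 brain capillary barrier genes, 4 were tested, and the amino acid transporter gene SLC7A8 alone stood above the median gene, at 55.4 CPM ± 30.3 and a log2 ratio of 2.16, which was 0.49 and not called without replicate 3. The lipid transporter gene MFSD2A had 2639, 17 and 51 reads and was called below the median gene without replicate 1, at -4.50. Neither list passed as a whole (camera adjusted p = 0.441 and 0.805). Nor did either pass the test of the share tested (17.6% and 36.4% against 25.8% of genes with a symbol, Fisher adjusted p = 0.744 and 0.721).

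Of 15 pericyte and smooth muscle genes, 3 were tested, and all 3 of them stood above the median gene: RGS5 at 273 CPM ± 334, TAGLN (ENSDARG00000033466) at 210.4 CPM ± 73.7 and rgs5b at 45.3 CPM ± 31.0. The RGS5 level rested on replicate 2, with 5590, 18235 and 765 reads and a mean of 83.3 CPM without it, and that of rgs5b was 29.2 CPM without replicate 3. The pericyte receptor gene PDGFRB had 1, 0 and 0 reads, and the smooth muscle actin gene acta2 had 4, 2 and 5. The list did not pass (camera adjusted p = 0.0711), though it did on YuGene scores (adjusted p = 0.0420; 0.0420 to 0.635 over the alternatives), and rgs5b lost its call without replicate 3, where its log2 ratio was 0.03, and with DESeq2.

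Immune cell genes differed between libraries. Of 35 macrophage and microglia genes, 10 were tested and 3 stood above the median gene: the MHC class II-associated invariant chain genes cd74a, at 296 CPM ± 231, and cd74b, at 134 CPM ± 221, and the oxidase gene cyba, at 117 CPM ± 88.8. Reads of cd74b were 58, 306 and 15963, and without replicate 3 its log2 ratio was -2.23, below the median gene and not called. DESeq2 and limma-trend did not call cd74b either. Without replicate 3 the mean of cd74b was 6.23 CPM and that of cd74a 169.8 CPM, and without replicate 2 that of cyba was 68.0 CPM. MPEG1 had 2, 1663 and 2028 reads, ptprc 8, 1 and 237, csf1ra 0, 3 and 102, and SPI1 7, 1500 and 14. The list did not pass (camera adjusted p = 0.805). Of 10 neutrophil genes 3 were tested and srgn stood above the median gene, at 55.2 CPM ± 11.6, a call lost without replicate 1 (log2 ratio of 1.34) and without replicate 3 (0.89; list, camera adjusted p = 0.856). Of 14 lymphocyte genes 2 were tested and 0 passed by edgeR, DESeq2 or limma-trend (0 at an unadjusted p under 0.05), with 0, 1664 and 156 reads of ighm.

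Among tested genes, those of neurons ranked low, and glial genes were uneven. Of 26 neuronal genes, 12 were tested and GNG3 alone stood above the median gene, at 81.0 CPM ± 50.2. The share tested was 46.2%, against 25.8% of genes with a symbol (Fisher p = 0.0241, adjusted p = 0.0614). The low rank therefore covers detected members alone and does not show that neuronal genes were detected less often. The median neuronal gene stood at -2.40 on the log2 scale against the median gene (camera adjusted p = 0.0410; estimated-correlation adjusted p = 0.493; 0.0355 to 0.879 over the alternatives). That call was lost without replicate 1 (adjusted p = 0.164) and without replicate 3 (adjusted p = 0.131). With no filter the median was 0.71, above the median gene. Without replicate 2 the filament gene nefla (18, 1006 and 10 reads) was called below the median gene, at -5.57. ELAVL3, an RNA-binding protein of neurons, had 1, 0 and 1 reads. Of 12 radial glia genes, 4 were tested and 2 stood above the median gene (2 above and 1 below adjusted over the list alone), ATP1B4 at 601 CPM ± 237 and FABP7 (ENSDARG00000007697) at 140.4 CPM ± 142, whereas the glial filament gene GFAP had 0, 1 and 0 reads (list, camera adjusted p = 0.700). Of the 19 symbols named for this list, 12 were matched. GLUL, whose 2 copies the symbol table does not tell apart, was not counted in it, and neither was the listed symbol cx43, so the count of high glial genes is incomplete. The list's median of 0.66 was 2.66 without replicate 1 and 1.70 without replicate 2, with 3 members tested in each case. With all copies of ambiguous names, 7 members were tested, the median was 2.92, and the list's adjusted p was 0.0575 (0.0575 to 0.884 over the alternatives). Of 13 oligodendrocyte genes, 5 were tested and the myelin genes mbpa, at 1122 CPM ± 856, plp1b, at 90.3 CPM ± 13.5, and mbpb, at 62.9 CPM ± 96.7, stood above the median gene. Without replicate 2 the means were 629 CPM for mbpa, 58.9 CPM for FABP7 and 52.6 CPM for GNG3. The mbpb value rested on replicate 2, with 4882 of its reads, and turned to -1.22 without it, with 1.56 and no call without replicate 3, and no call with DESeq2, limma-trend or shared reads removed (list, camera adjusted p = 0.393).

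Of 23 fibroblast and meningeal genes, 13 were tested, a larger share than of other genes with a symbol (56.5% against 25.8%, Fisher adjusted p = 0.0110). Among cell type lists, only the lymphatic and pan-endothelial ones also passed that test with a larger share. Other cell type lists had larger shares that did not pass, such as the neuron list at 46.2% (Fisher adjusted p = 0.0614). PDGFRA stood above the median gene at 38.8 CPM ± 12.6, with 0 when adjusted over the list alone, and lost its call without replicate 1 (log2 ratio of 0.96) and without replicate 3 (0.22), with DESeq2 and with shared reads removed. The transporter gene SLC13A4 was not called, but was without replicate 2 (1.42) and with no filter (7.04) (list, camera adjusted p = 0.158). Of 10 ependymal genes 3 were tested and cfap126 passed at 41.9 CPM ± 42.4 (list, camera adjusted p = 0.805). That call was lost without replicate 1 (log2 ratio of 1.17), replicate 2 (0.05, with a mean of 17.5 CPM) and replicate 3 (0.84), and with DESeq2, limma-trend and shared reads removed. Of 12 keratinocyte and epithelial genes 2 were tested, of 15 pigment cell genes 1 and of 7 thrombocyte genes 1, and 0 of these passed by edgeR, DESeq2 or limma-trend (0 at an unadjusted p under 0.05). Of 11 erythrocyte and 8 skeletal muscle genes, 0 reached the filter, with 0, 2 and 112 reads of the globin gene hbaa1.

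The lymphatic list lay above 6 lists of other cells in every library, and below the pan-endothelial list in replicates 1 and 3. Its median exceeded that of the blood and arterial endothelial list by 4.97 ± 0.68 on the log2(CPM + 1) scale (SD, n = 3, exact sign-flip permutation p = 0.25, the smallest that 3 libraries allow). The difference was 4.92 ± 0.73 against the brain capillary barrier list, 4.83 ± 0.61 against macrophages and microglia, 4.97 ± 0.70 against pericytes and smooth muscle, 4.72 ± 0.67 against neurons and 4.91 ± 0.64 against radial glia, each positive in 3 of 3 libraries. The pan-endothelial list exceeded the macrophage and microglia list by 5.02 ± 0.08 and the pericyte and smooth muscle list by 5.16 ± 0.25. The medians of the other lists lay between 0.01 and 0.26, near the floor, so these differences mostly give the level of the endothelial lists and depend on the pseudocount. With members under 3 reads set to 3 reads and no pseudocount, the difference was at least 8.49 against the blood and arterial list, whose median lay at the floor. Over the 8 pairs it was 7.46 to 8.69, a lower bound wherever the other median lay at the floor. With tested members alone it was 1.84 against the blood and arterial list, 2.47 against macrophages and microglia and 1.32 against radial glia. Among tested members, the radial glia median was above the lymphatic one without replicate 1 (2.66 against 1.44 over the median gene). It was also above it with all copies of ambiguous names (2.92 against 1.85), and below it without replicate 2 (1.70 against 3.24). Against the pericyte list, the order turned when members under the filter were left out (-1.26 for the lymphatic and -1.54 for the pan-endothelial list).

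**Figure D2:**
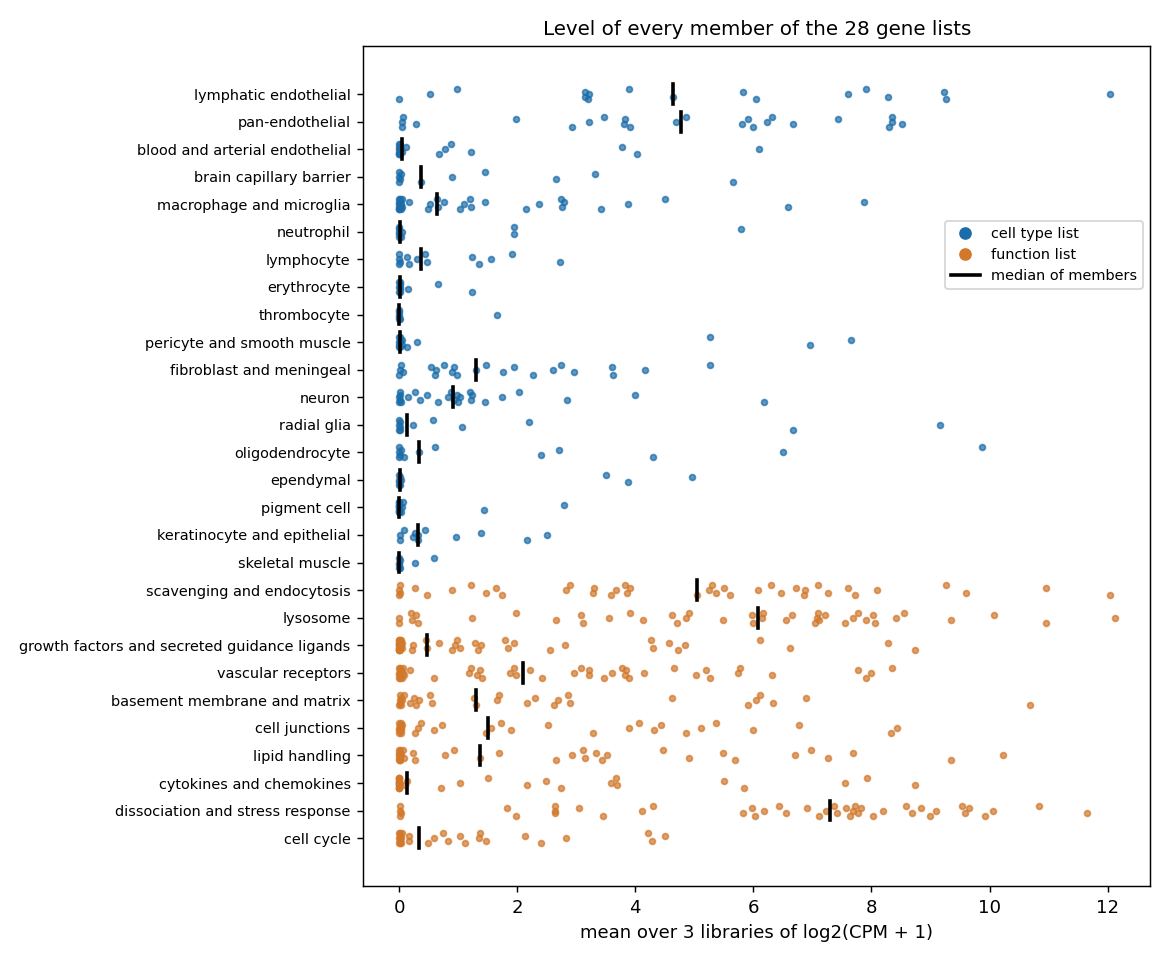
Level of every matched member of the 28 lists, each point a gene at its mean log2(CPM + 1) over 3 libraries, with cell type lists in blue, function lists in orange and the median of each list as a black bar. The lymphatic and pan-endothelial medians lie apart from those of the other cell type lists, which lie under 2 units.

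Genes of uptake and breakdown stood high. Of 42 lysosomal genes, 35 were tested and 25 stood above the median gene (26 adjusted over the list alone), with 0 below. They were led by the protease gene ctsla at 4510.4 CPM ± 888 (SD, n = 3), the legumain gene LGMN at 2030.2 CPM ± 496, CD63 at 1089.5 CPM ± 213 and NPC2, a sterol carrier, at 659.7 CPM ± 119. The list passed at a camera adjusted p of 5.81e-09 (estimated-correlation adjusted p = 0.207; 6.98e-15 to 0.207 over the alternatives), with a median of 2.92 that was 2.34 without replicate 1 and 2.00 without replicate 3. Of 41 scavenging and endocytosis genes, 31 were tested and 21 stood above the median gene (21 adjusted over the list alone). Beside MRC1, LGMN and stab2, these included the sorting nexin gene SNX5 at 774 CPM ± 53.2 (camera adjusted p = 8.45e-06; estimated-correlation adjusted p = 0.227; 2.94e-10 to 0.227 over the alternatives), with a median of 1.87 that was 0.96 without replicate 1. This list shares 3 members with the cell type lists. Of 37 lipid handling genes, 18 were tested and 8 stood above the median gene (9 adjusted over the list alone), among them the apolipoprotein gene apoeb at 1360.4 CPM ± 882, the acid lipase gene LIPA at 219 CPM ± 102 and plin3 at 155 CPM ± 34.9. Without replicate 3 the mean of apoeb was 857 CPM. That list passed at a camera adjusted p of 0.0410 (estimated-correlation adjusted p = 0.557; 0.0331 to 0.557 over the alternatives). The call was lost without replicate 1 (adjusted p = 0.164), replicate 2 (0.200) and replicate 3 (0.131).

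The highest list was that of dissociation and stress genes. An effect of dissociation may bear on every level above, but it was not tested, for lack of an undissociated sample. Of the list's 44 genes, 39 were tested and 31 stood above the median gene (31 adjusted over the list alone). The RNA decay factor gene ZFP36L1 stood at 3285 CPM ± 730.3, the chaperone gene dnajb1b at 1992 CPM ± 1049.8, and the immediate early genes ier2a and JUNB at 1139 CPM ± 477 and 1101 CPM ± 694, the last with a mean of 712 CPM without replicate 3. The list passed at a camera adjusted p of 2.39e-11 (estimated-correlation adjusted p = 0.207; 1.75e-16 to 0.207 over the alternatives), with a median of 3.83 that was 3.03 without replicate 1 and 2.90 without replicate 3.

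Secreted ligands held a few high members but did not stand apart from other genes as a list. Of 46 growth factor and guidance genes, 15 were tested and 4 stood above the median gene: the chemokine gene CXCL12 at 438 CPM ± 131, ANGPT2, ANGPTL4 at 109 CPM ± 66.9 and VEGFA (ENSDARG00000034700) at a log2 ratio of 2.50 ± 0.45 (SE). The share tested was 32.6%, against 25.8% of genes with a symbol (Fisher adjusted p = 0.545). Of all 7111 tested genes, 1666 stood above the median gene. The VEGFA call was lost without replicate 3 (1.42), and ANGPTL4 had a mean of 70.9 CPM without replicate 2. The VEGFA level was not highest in replicate 3 (92.8, 49.3 and 68.5 CPM), so that loss does not rest on a high level there. The other VEGFA copy had 1, 407 and 1 reads. VEGFC had 0, 0 and 255 reads, VEGFD 7, 3 and 522, pdgfbb 1, 2 and 1, and vegfba 0 in each library, and PDGFA did not pass at 24.1 CPM ± 10.5 (list, camera adjusted p = 0.413). Of 29 cytokine and chemokine genes, 11 were tested and 5 stood above the median gene, including ccl25b at 246 CPM ± 49.4, cxcl18b at 197 CPM ± 80.4 and CXCL14 at 58.2 CPM ± 17.6, the last not called without replicate 3 (log2 ratio of 0.90; list, camera adjusted p = 0.158, and 0.00883 with no filter; 0.00883 to 0.519 over the alternatives). The list's median was -0.06 and its mean 1.11, and the median turned to 0.75, 1.63 and 0.85 without replicates 1, 2 and 3. Only 10, 8 and 7 of the 11 members were then tested, so these medians are not of the same members.

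Of 48 vascular receptor genes, 29 were tested and 8 stood above the median gene, with the chemokine scavenger gene ACKR3 at 307 CPM ± 278, the endothelin receptor gene EDNRA at 258 CPM ± 55.0 and FLT4 (list, camera adjusted p = 0.317, and 0.00699 with no filter; 0.00699 to 0.738 over the alternatives). This list shares 16 members with the cell type lists. Of 31 basement membrane and matrix genes, 15 were tested and 6 stood above the median gene (6 above and 1 below adjusted over the list alone), led by the protease inhibitor gene TIMP2 (ENSDARG00000061226) at 1763 CPM ± 808 and MMP2 at 123 CPM ± 46.7 (list, camera adjusted p = 0.459; median -0.78 and mean 0.52). The median turned positive without replicate 1 (1.12), replicate 2 (1.67) and replicate 3 (1.28), with 13, 8 and 8 of the 15 members tested. These medians are therefore not of the same members. The list passed without replicate 2 (camera adjusted p = 0.0355), where col18a1a lost its call (1.26). Over the alternatives the camera adjusted p ran from 0.0355 to 0.884. Of 32 junction genes, 15 were tested and 5 stood above the median gene (7 adjusted over the list alone), among them GJA1 at 446 CPM ± 401 and CTNND1 at 422 CPM ± 389 (list, camera adjusted p = 0.158). Without replicate 2 the means were 154 CPM for ACKR3, 216 CPM for GJA1 and 198 CPM for CTNND1. Of 30 cell cycle genes, 6 were tested and 0 passed by edgeR, DESeq2 or limma-trend (0 at an unadjusted p under 0.05), with PCNA at 25.4 CPM ± 16.9 (16.3 without replicate 1) and MCM4 at 32.1 CPM ± 33.3 (13.9 without replicate 2; list, camera adjusted p = 0.856).

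Some genes of substantial mean level were carried by a single pool of brains or by a pair of them. Among genes with a symbol and a mean of at least 50 CPM, the 8 largest ratios between libraries were those of CARTPT, IRF7, REEP2, znf346, si:dkey-238d18.4, TST, SWAP70 and C3H16orf89. CARTPT, a neuropeptide gene, had 6235, 423 and 0 reads, and REEP2 had 4, 6659 and 528. The interferon factor gene IRF7 had 2, 3336 and 1662 reads, and SWAP70 had 8, 2371 and 3251. REEP2, znf346, TST, SWAP70 and C3H16orf89 were called above the median gene by edgeR and the other 3 were not. None of these 5 calls held with DESeq2 or limma-trend, and with limma-trend REEP2 stood at -0.79, znf346 at -0.93, TST at -0.087 and SWAP70 at -0.11. None of the 5 held with shared reads removed. Without replicate 2, znf346 stood at -2.81 and TST at -0.19, both not called, and the mean of REEP2 was 6.47 CPM. Without replicate 3, the calls of znf346 (1.81), TST (1.48) and C3H16orf89 (0.93) were lost, and without replicate 1, IRF7 (1.72) and si:dkey-238d18.4 (1.69) were called.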

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

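Removal of shared reads, all copies of ambiguous names, the list without lyve1b, the 3-read floor and Fisher's exact test of list detection were chosen after the data were seen. The other alternatives were planned. No paired analysis was possible because the labels give a single group. The gene-length alternatives were not run, since no gene lengths were used here. Over the named genes, 833 values kept their call, 76 lost a call and 27 gained one. A further 23 changed direction with a call in the main or the alternative setting. Values called in neither setting were counted as kept whatever their direction. The cause was not tested except where stated. The 8 list pairs stayed positive under every alternative run except the filter on members, which left -1.26 (lymphatic) and -1.54 (pan-endothelial) against pericytes and smooth muscle, by leaving out the undetected pericyte genes. The number of genes detected was 4091 with filterByExpr, 3426 at 1 CPM in all libraries, 18455 at 1 read in any, and 4444 to 5818 leaving out 1 library. The replicate agreement, the mean Pearson's r, was 0.712 with no filter, 0.701 with filterByExpr and 0.637 to 0.767 leaving out 1 library. Genes above the median gene numbered 1038 with filterByExpr, all among the 1666 of the report, 8404 with no filter, 789 against the 75th percentile and 937 to 1580 leaving out 1 library. Genes below numbered 216 with filterByExpr, 244 with limma-trend, 35 with shared reads removed and 215 to 480 leaving out 1 library. Of the 88 of the report, 4 were tested with filterByExpr and 23, 56 and 17 without replicates 1, 2 and 3. Most genes below in those settings were therefore other genes. They numbered 0 with no filter (edgeR, 0 at an unadjusted p under 0.05) and 0 with DESeq2 (75 at an unadjusted p under 0.05). Lists ranked higher numbered 0 with an estimated correlation. Lists ranked lower numbered 0 with an estimated correlation, YuGene scores, no filter and all copies of ambiguous names, and 0 to 1 leaving out 1 library. With no filter the reference median is lower by construction, so the neuron list stood at 0.71 and these genes turned upward: ABCB9 5.91, MMP9 5.31, cd79a 7.15, ITGB3 (ENSDARG00000045070) 4.71, SNAP25 (ENSDARG00000058117) 6.65, cnp 6.55, RSPH9 7.23, TFEC 6.27, TP63 7.47, krt15 5.16, TYMS 7.88 and sox18 6.53. Against the 75th percentile, a higher reference, cfap126 stood at -0.033. With limma-trend, REEP2 stood at -0.79, znf346 at -0.93, TST at -0.087 and SWAP70 at -0.11. Leaving out 1 library gave MFSD2A -4.50 (without replicate 1) to 1.00, cd74b -2.23 (without replicate 3) to 3.57, and, lowest without replicate 2, the gene nefla -5.57 to -0.55, mbpb -1.22 to 1.84, znf346 -2.81 to 1.94 and TST -0.19 to 1.96.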

Other observations

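The test of absence by level was set before its result was seen; the other tests below were chosen after. Outside the naming rule, and chosen after their values were seen, the MHC class I genes mhc1zba and b2ml stood at 2903 CPM ± 561 and 1030.3 CPM ± 524 (SD, n = 3). The retinol carrier gene RBP4 stood at 1038 CPM ± 179.9, and etsrp, a vascular ETS factor gene that the pan-endothelial list names by another symbol, at 448 CPM ± 73.3. The summed CPM of the fibroblast list genes came to 0.245%, 0.322% and 0.248% of the CPM of epd in replicates 1, 2 and 3.

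Many genes with 1000 or more reads in a library had a small count in another; genes were taken as held by a library where both other counts were under 2% of its count, a limit chosen after the data were seen. The median ratio into replicate 2 was 0.698% for 63 genes held by replicate 1 and 0.133% for 118 held by replicate 3 (permutation p = 1e-05, the smallest the permutations can give). Reads passing between the libraries may therefore account for part of the small counts in replicate 2. Into replicate 1 the median ratios were 0.0882% for genes held by replicate 2 and 0.165% for those held by replicate 3. Into replicate 3 they were 0.0592% for genes held by replicate 1 and 0.152% for those held by replicate 2. The test covered replicate 2 alone. Low true expression stays open: in bins of 0.5 log10 units, the gap in the ratios held 0.596, 0.33 and 0.641 of the genes of its neighbours in replicates 1, 2 and 3, and bins of 0.25, tried after that result, gave 0.248, 0.165 and 0.283 against the lower peak. Removing counts under that limit took out 0.0158%, 0.0425% and 0.00957% of reads; no biological explanation was tested.

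Genes were often present in a library and absent from another. With 100 or more reads in a library and 0 in another there were 3172 cases, where Poisson sampling at these depths gives 1.55e-13, so sequencing depth does not account for them. The share absent, counting as absent what lay under 2% of another library's count, was 30.9% at 10 to 50 CPM, 6.49% at 50 to 200, 0.481% at 200 to 500 and 0.108% above 500 CPM. Few starting molecules per gene before amplification may account for this fall. No biological explanation was tested, and differences between the pools of fish stay open.

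The neuropeptide genes gnrh2, which lies outside the naming rule and was chosen after its values were seen, and CARTPT were high in replicate 1. Reads of gnrh2 were 124093, 8278 and 815, and those of CARTPT 6235, 423 and 0, or 19.9 and 19.6 reads of gnrh2 per read of CARTPT in replicates 1 and 2. Their ratios of replicate 2 to replicate 1, 6.67% and 6.78%, are near each other, as a common transfer would give, but at a rate of 6.67% for every gene 416 of 2298 other genes with 1000 or more reads in replicate 1 had too few reads in replicate 2 (Poisson p under 0.001, 2.30 by chance). At the gnrh2 ratio of replicate 3, 0.657%, 39 genes had too few reads in replicate 3, and CARTPT had 0 where 40.9 would be needed, so a common rate is argued against in both libraries, while transfer at a rate of its own for each gene may still have a part. The neuron list sum was lowest in replicate 1 (85.2, 245 and 118 CPM), but GNG3 alone gave 42.5, 138 and 62.7 CPM of it. The sum therefore cannot decide whether whole neurons were in the sort. There was 1 neuron list member at 10 CPM or more in replicate 1 and higher there than in the other libraries. Whole neurons in the sort stay open, because the level of gnrh2 in a neuron is not known here. No biological explanation was tested.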
